A study of Capra hircus with 6 samples.

How the data were processed

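Small RNA was sequenced from the nasal tissue of 3 Nanjiang yellow goats, a Chinese meat breed. From each goat 1 library came from an enzootic nasal adenocarcinoma, a glandular tumor of the nasal cavity of goats, and 1 from para-carcinoma tissue, the tissue taken beside the tumor. Per the labels' protocols, RNA was extracted with Trizol, a gel fraction of 18-30 nt was kept, adaptors were ligated to each end, and libraries were made with the Illumina TruSeq small RNA kit. Per the series' design text, sequencing was done on an Illumina HiSeq instrument. Per the submitters' processing notes, Bowtie 0.12.2 was used. The genome build, the miRNA annotation and its version, the treatment of reads that match several miRNAs, and any trimming or mismatch setting are not given in the sources used here.

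Each deposited file held, per the file headers, a read count and a TPM value for each of 452 features in 1 library. The deposited counts were whole numbers and were used as raw counts. The deposited TPM values equalled the count divided by the library's total count, scaled as CPM is, with no term for length. They were used only for that check. Of the 452 features, 406 carried a goat miRNA name and 46 were named by a sequence contig and a number. Contig names are printed as the files give them. The goat gene table used here was of assembly ARS1.2, and the files name no build, so no coordinates are given. The table served only to find which hairpins lie within 10 kb of each other, and 252 of the 255 hairpin names in the files matched 1 entry.

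The total count per library ranged from 851539 to 2597732. A count of 0 allows up to 3 reads, which corresponds to between 1.15 and 3.52 CPM of a library's total. The widest half-width of the 95% Wilson interval of a library's largest share was 0.0877 percentage points. Reads carried no molecular identifiers in the sources used here, so such intervals and floors cover counting error only. Counts of any 2 libraries of a group differed far beyond sampling noise (chi-square per degree of freedom of at least 126), so no library was treated as a duplicate.

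Differences between groups were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr with the group, and the quasi-likelihood F test of tumor against para-carcinoma over all 6 libraries, with no other term. The p-values were adjusted by Benjamini and Hochberg, and the threshold was 0.05. Of the 452 features, 275 passed the filter and were tested. They held at least 99.9% of the reads of each library. Standard errors of log2 fold changes were derived from the F statistic. Abundances are CPM, counts scaled to the TMM-corrected library size, as mean ± SD of 3 libraries. For miRNAs with 1 to 3 reads in a group, the fitted fold depends on the prior count. For these the ratio of reads summed over the 3 libraries of a group is given with its exact binomial interval. That interval covers counting error only and leaves out the spread between goats.

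The 15 miRNA lists were fixed before the data were examined, from general knowledge, for cell types that nasal tissue can hold and for miRNA families often studied in carcinomas. The 12 lists with at least 3 tested members were tested with camera in limma 3.58.1, at a preset correlation of 0.01, two-sided and adjusted over the 12 lists. Only 1 tested feature, miR-155-5p, was in 2 lists. Arm usage was tested with limma on the log2 ratio of the 5p to the 3p count, with a pseudocount of 0.5. Shares of reads were compared by a two-sided exact permutation test, for which 3 against 3 libraries give no p below 0.1.

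The miRNAs named in the text were chosen by a rule fixed at the same time. Among those past the threshold with the same sign in all 3 goats, it took the 8 largest rises, the 8 largest falls and the 6 most abundant. It added the 5 most abundant features overall and, per list, the 2 most abundant tested members with up to 2 further members of smallest adjusted p. A miRNA named outside this rule is marked as named after its value was seen.

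The same goat number in the labels means the same animal, so the numbers pair the samples. Deviations from the group means correlated across miRNAs with r = 0.28, -0.05 and -0.17 between the libraries of goats 1, 2 and 3. The fit with the goat as a block was an alternative, and its edgeR value stands beside a result where it changed the call. Other alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, stricter thresholds, other set tests, and leaving out each library or goat. Summing features with near-equal counts was added after seeing the data.

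The tests were checked on simulated counts for the tumor and para-carcinoma comparison, with the means, dispersions and library sizes of the 275 features. Each of 20 simulations changed 120 features. Of those changed 2-fold, 61.5% were called, of 4-fold 98.5% and of 8-fold 100%. Unchanged features were called in 2.06% of cases and made up 2.96% of calls. Rises and falls were planted in equal numbers, so these rates do not cover an error of the scaling. A list of 8 features lowered 4-fold was called in 100% of simulations and random lists in 1.5%. Each simulated feature was drawn independently, so these list rates do not cover correlation between miRNAs. In the data it was estimated at 0.63 for the multiciliated, 0.15 for the let-7 and 0.13 for the smooth muscle and fibroblast list. A 4-fold change of the arm ratio was called in 76.2% of cases, with 0.6 false calls per simulation.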

Results

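The abundance of mature miRNAs, short RNAs that repress messenger RNAs, was measured in 3 nasal tumors and in the 3 para-carcinoma tissues of the same goats. The comparison asked which miRNAs differ between enzootic nasal adenocarcinoma and the tissue beside it. The tumor libraries of goats 1, 2 and 3 held 2597732, 1444169 and 896501 reads, and the para-carcinoma libraries 2576052, 851539 and 1285635. Each goat gave 1 library per tissue, so p-values rest on the spread between 3 animals per group. Across miRNAs, log2 abundances correlated with r between 0.972 and 0.985 within a group and between 0.850 and 0.894 across groups.

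A different miRNA led each tissue. In para-carcinoma tissue miR-143-3p, known from smooth muscle and fibroblasts, held 38.7% ± 15.04 of the reads (SD, n = 3), against 5.55% ± 1.17 in tumors. In tumors miR-148a-3p, known from secretory and glandular epithelia, held 23.9% ± 2.59, against 3.79% ± 0.218 in para-carcinoma tissue. Neither group overlapped the other for these miRNAs, and the exact permutation p was 0.1 for each, the smallest that 3 against 3 can give. The share of whichever miRNA led a library did not differ beyond the spread, at 14.8 percentage points less in tumors (difference -14.8, exact permutation p = 0.3). Para-carcinoma libraries were the more variable, with miR-143-3p at 43.6% (95% Wilson interval 43.6 to 43.7), 21.8% (21.7 to 21.9) and 50.6% (50.5 to 50.7) in goats 1 to 3. The 10 most abundant miRNAs together held 71.4% ± 1.01 of tumor reads and 75.8% ± 7.65 of para-carcinoma reads (exact permutation p = 0.4).

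Of 275 miRNAs tested, 70 were higher and 67 lower in tumors in the edgeR test. Of these, 63 and 67 had the same sign in all 3 goats. Among the most abundant, miR-143-3p fell from 491003 ± 237619 CPM to 46249 ± 11889, a log2 fold change of -3.41 ± 0.42 (SE, edgeR adjusted p = 7.0e-05). The abundance of miR-148a-3p rose from 46177 ± 6626 to 197746 ± 28387 CPM (2.10 ± 0.25, edgeR adjusted p = 5.9e-05). A member of the HOX-cluster miRNAs, miR-10b-5p, fell 8.56-fold, from 46957 ± 1919 to 5489 ± 2086 CPM. Smaller changes were seen for let-7a-5p, which rose 2.82-fold, and miR-27b-3p, which fell 1.69-fold (edgeR adjusted p = 0.018). The other 2 of the most abundant miRNAs, miR-26a-5p and miR-21-5p, did not pass, at log2 fold changes of -0.66 ± 0.27 (edgeR adjusted p = 0.057) and 0.42 ± 0.29 (0.26). With library totals miR-21-5p was higher (log2 0.93, edgeR adjusted p = 0.023). Other settings lowered the edgeR adjusted p of miR-26a-5p below the threshold, to 0.044 with DESeq2 size factors, 0.041 without the para-carcinoma library of goat 3 and 0.046 with near-equal features summed.

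The largest falls were those of miR-449a-3p, miR-133a-3p, miR-449b-5p, miR-449c, miR-449a-5p, miR-34c-3p, miR-190b and NC_022308.1_285. Among these, miR-133a-3p, known from striated muscle, went from 232 ± 136 to 3.51 ± 1.26 CPM (-6.09 ± 0.62). In the same group miR-190b went from 39.4 ± 25.7 to 2.10 ± 1.22 CPM (-4.33 ± 0.69), and the contig-named NC_022308.1_285 from 183 ± 69.2 to 9.96 ± 5.70 CPM (-4.27 ± 0.45). The 8 largest rises included those of miR-148a-3p and miR-9-5p. Among the other 6, miR-135a rose from 3.31 ± 1.93 to 43.8 ± 14.9 CPM (3.63 ± 0.49), miR-331-3p from 0.730 ± 1.26 to 10.8 ± 0.508 CPM (3.28 ± 0.74) and miR-296-3p from 45.2 ± 16.5 to 273 ± 27.6 CPM (2.59 ± 0.33). The 4 para-carcinoma reads of miR-331-3p were all from goat 1, so the size of its fold is uncertain. With 3 para-carcinoma reads each, miR-323b was 15.8 times as abundant in tumors (95% binomial interval 5.21 to 78.4) and miR-873-3p 10.8 times (3.50 to 54.1). The contig-named NC_022318.1_749 rose from 47.3 ± 19.7 to 226 ± 181 CPM (2.26 ± 0.55), by 1.98, 3.81 and 0.22 (log2) in goats 1 to 3. Without the tumor of goat 2 its log2 fold change was 1.37 (edgeR adjusted p = 0.021), and without both libraries of goat 1 it did not pass (2.31, edgeR adjusted p = 0.082). In the tumors NC_022318.1_739 and NC_022318.1_745 (named after their values were seen) had abundances close to those of NC_022318.1_749. Both were lower in the tumor of goat 3, at 76.6 against 82.7 CPM and 89.7 against 91.6 CPM, so the rise in that goat is uncertain.

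The split of calls depended on the scaling. With library totals in place of TMM, which shifts the median log2 fold change by 0.54, 106 were higher and 40 lower, so 72.6% of calls were rises against 51.1% with TMM. All changes here are relative to the TMM scale. Without both libraries of goat 1 the count of rises fell to 32, and without goat 3 to 45. With library totals miR-27b-3p no longer passed (log2 -0.21, edgeR adjusted p = 0.54), and without the tumor of goat 2 or of goat 3 its edgeR adjusted p was 0.065 and 0.087.

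**Figure D1:**
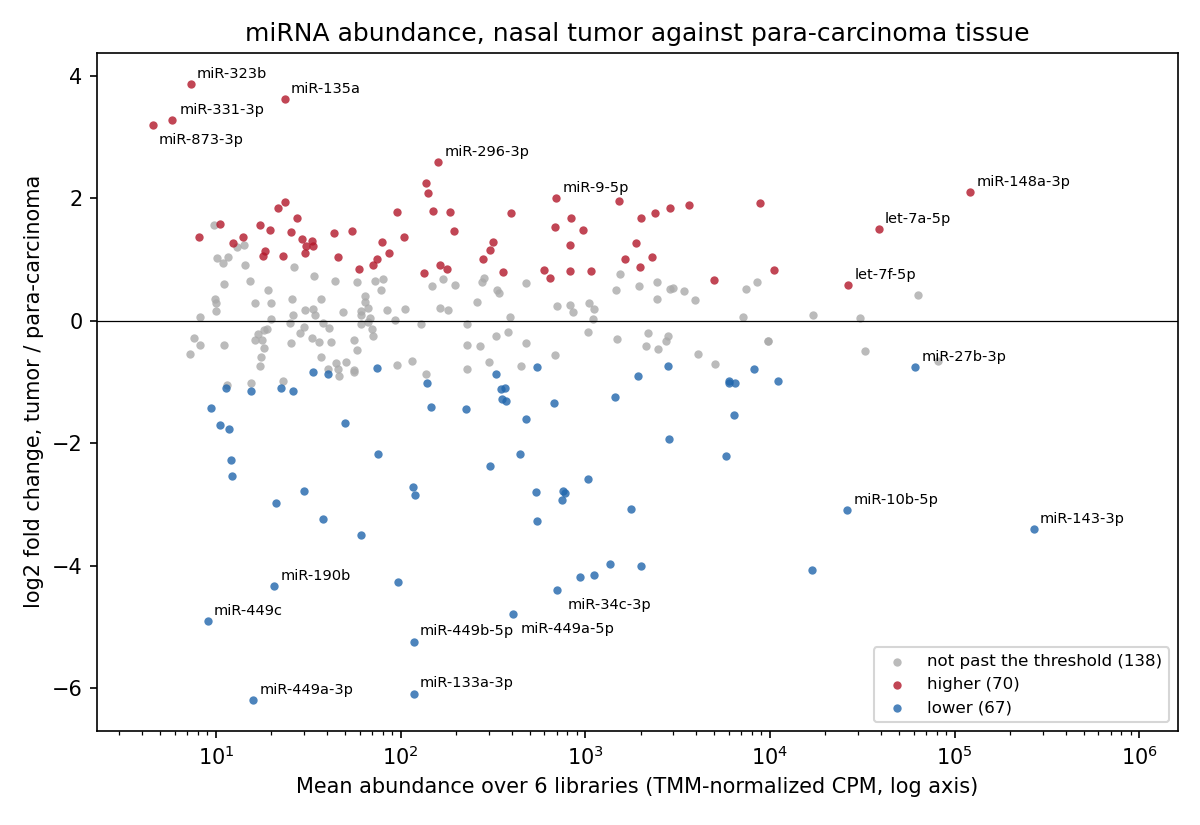
Each point is 1 of the 275 tested miRNAs, placed by its mean abundance over the 6 libraries (CPM, log axis) and its log2 fold change of tumor over para-carcinoma; color marks the 70 higher, the 67 lower and the 138 that did not pass. The fitted folds of miRNAs with 1 to 3 reads in a group, such as miR-449a-3p, depend on the prior count.

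The miRNAs of multiciliated cells were all lower in tumors. All 8 tested members of that list, made up of the miR-34b/c and miR-449 families that act in the formation of motile cilia, fell, with a median log2 fold change of -4.60. The most abundant, miR-34c-5p, fell from 32034 ± 20683 to 1917 ± 682 CPM (-4.06 ± 0.47, edgeR adjusted p = 4.7e-05). Its 3p arm fell from 1342 ± 548 to 63.9 ± 24.2 CPM, and miR-34b-5p from 2112 ± 1058 to 120 ± 48.9 CPM. Likewise miR-449a-5p fell from 780 ± 326 to 29.0 ± 21.3 CPM and miR-449b-5p from 230 ± 140 to 6.47 ± 4.22 CPM. With 2 and 3 tumor reads, miR-449a-3p was 89.7 times (95% binomial interval 24.3 to 750.2) and miR-449c 32.6 times (10.6 to 162) as abundant in para-carcinoma tissue. With both at the lower end of these intervals, which leave out the spread between goats, the list median was -4.29. The list passed camera (adjusted p = 1.2e-08) but not with an estimated correlation (adjusted p = 0.28). All 8 members were also lower adjusted over the list alone.

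Most miRNAs of smooth muscle and fibroblasts were lower too. Of 11 tested members 10 fell, also adjusted over the list alone, and the median log2 fold change was -2.78. Besides miR-143-3p, its cluster neighbor miR-145-3p fell from 2562 ± 1408 to 163 ± 15.9 CPM (-3.98 ± 0.42), miR-199a-5p from 989 ± 181 to 103 ± 35.1 CPM (-3.26 ± 0.34) and miR-199b-5p from 203 ± 34.3 to 31.0 ± 10.5 CPM (-2.72 ± 0.33). The member that did not pass was miR-424-5p (-0.10 ± 0.61, named after its value was seen). The list passed camera (adjusted p = 4.5e-06) but not with an estimated correlation (adjusted p = 0.28). With library totals 9 members were lower. Counts of the members miR-199a-3p and miR-199b-3p (named after their values were seen) lay within 0.25 (log2) of each other in each library. They may therefore not be separate members. With near-equal features summed the list passed camera (adjusted p = 1.9e-05).

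Markers of some other cell types changed as well, not all in the same direction. Both tested striated muscle members changed, in opposite directions: miR-133a-3p as above, and miR-499-5p rose from 9.65 ± 5.98 to 33.9 ± 7.83 CPM (1.84 ± 0.44). The endothelial miR-126-5p fell from 14713 ± 2840 to 7448 ± 2069 CPM (-0.98 ± 0.28, edgeR adjusted p = 0.015) and miR-126-3p from 689 ± 151 to 407 ± 32.3 CPM (-0.76 ± 0.27, edgeR adjusted p = 0.037, with the goat as a block 0.053). The red blood cell miRNAs miR-451-5p (-1.12 ± 0.38, edgeR adjusted p = 0.034) and miR-144-3p (-1.10 ± 0.40, 0.041) fell as well. These 3 lists had under 3 tested members and no list test. With library totals none of the 4 endothelial and red blood cell miRNAs passed, at list medians of -0.34 and -0.54. With 1 library left out, calls were lost at folds that kept their sign. Without the tumor or the para-carcinoma library of goat 3, miR-126-5p was at -0.76 and -0.81 (edgeR adjusted p = 0.081 and 0.056). Its 3p arm was between -0.58 and -0.84 without any 1 library except the para-carcinoma library of goat 3 (edgeR adjusted p of up to 0.12). The fold of miR-451-5p was between -0.88 and -1.14 (log2) without the tumor of goat 2 or 3 or the para-carcinoma library of goat 1 or 3 (edgeR adjusted p between 0.075 and 0.12). Without any 1 library except the tumor of goat 3, miR-144-3p was between -0.82 and -1.22 (edgeR adjusted p between 0.060 and 0.12).

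Of 7 leukocyte members 2 fell, 1 of them adjusted over the list alone, and none rose. A miRNA induced by NF-kB, miR-146a, fell from 9539 ± 4609 to 2056 ± 613 CPM (-2.21 ± 0.36, edgeR adjusted p = 0.00049), and miR-342-3p from 500.5 ± 272 to 233 ± 71.9 CPM (-1.10 ± 0.39, 0.038). Values of miR-146b-5p (-0.47 ± 0.33, edgeR adjusted p = 0.26) and miR-155-5p (-0.73 ± 0.35, 0.098) did not pass, nor did the list (camera adjusted p = 0.57). Lower in all 3 goats, miR-155-5p did pass in DESeq2 with the goat as a block (log2 -0.71, DESeq2 adjusted p = 0.042). With library totals the list median was -0.10 instead of -0.56, with 3 of 7 members above 0 and 1 called lower. The call of miR-342-3p was lost with library totals (log2 -0.66, edgeR adjusted p = 0.24). It was also lost without the tumor of goat 1 or 3 (0.12 each) or the para-carcinoma library of goat 2 (log2 -0.55, edgeR adjusted p = 0.19).

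Cartilage members split by hairpin: the 3p and 5p arms of miR-140, which acts in cartilage growth, fell (-1.61 ± 0.27 and -1.15 ± 0.37), and those of miR-455 rose (1.47 ± 0.36 and 1.01 ± 0.38). The list did not pass (camera adjusted p = 0.99), with 2 of 4 members in each direction, also adjusted over the list alone, and its median was -0.07, or 0.46 with library totals. The rise of miR-455-5p was seen in goats 1 and 2, while in goat 3 the tumor had 57.5 CPM against 62.0, and with the goat as a block it no longer passed (edgeR adjusted p = 0.075). Its edgeR adjusted p was between 0.069 and 0.16 without either library of goat 1, the tumor of goat 2 or the para-carcinoma library of goat 2. Without the tumor of goat 1 or 2 or the para-carcinoma library of goat 1 or 2, that of miR-140-5p was between 0.051 and 0.11, and with library totals 0.29. Of 4 neuronal members, miR-9-5p rose from 278 ± 221 to 1116 ± 900 CPM (2.00 ± 0.63, edgeR adjusted p = 0.023) and miR-153 fell from 16.3 ± 3.40 to 4.69 ± 1.30 CPM (-1.70 ± 0.43), the same counts as adjusted over the list alone. The other 2, miR-128-3p and miR-128-5p, had values of 0.30 ± 0.26 and -0.39 ± 0.46. The list did not pass (camera adjusted p = 0.99), and its median was -0.05 and its mean 0.05. With library totals the median was 0.50 and 3 of 4 members were above 0, with miR-9-5p the only call. Without the tumor of goat 1 the log2 fold change of miR-9-5p was 1.11 (edgeR adjusted p = 0.14), and without the para-carcinoma library of goat 2 or 3 its adjusted p was 0.086 and 0.095. With library totals the edgeR adjusted p of miR-153 was 0.072.

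**Figure D2:**
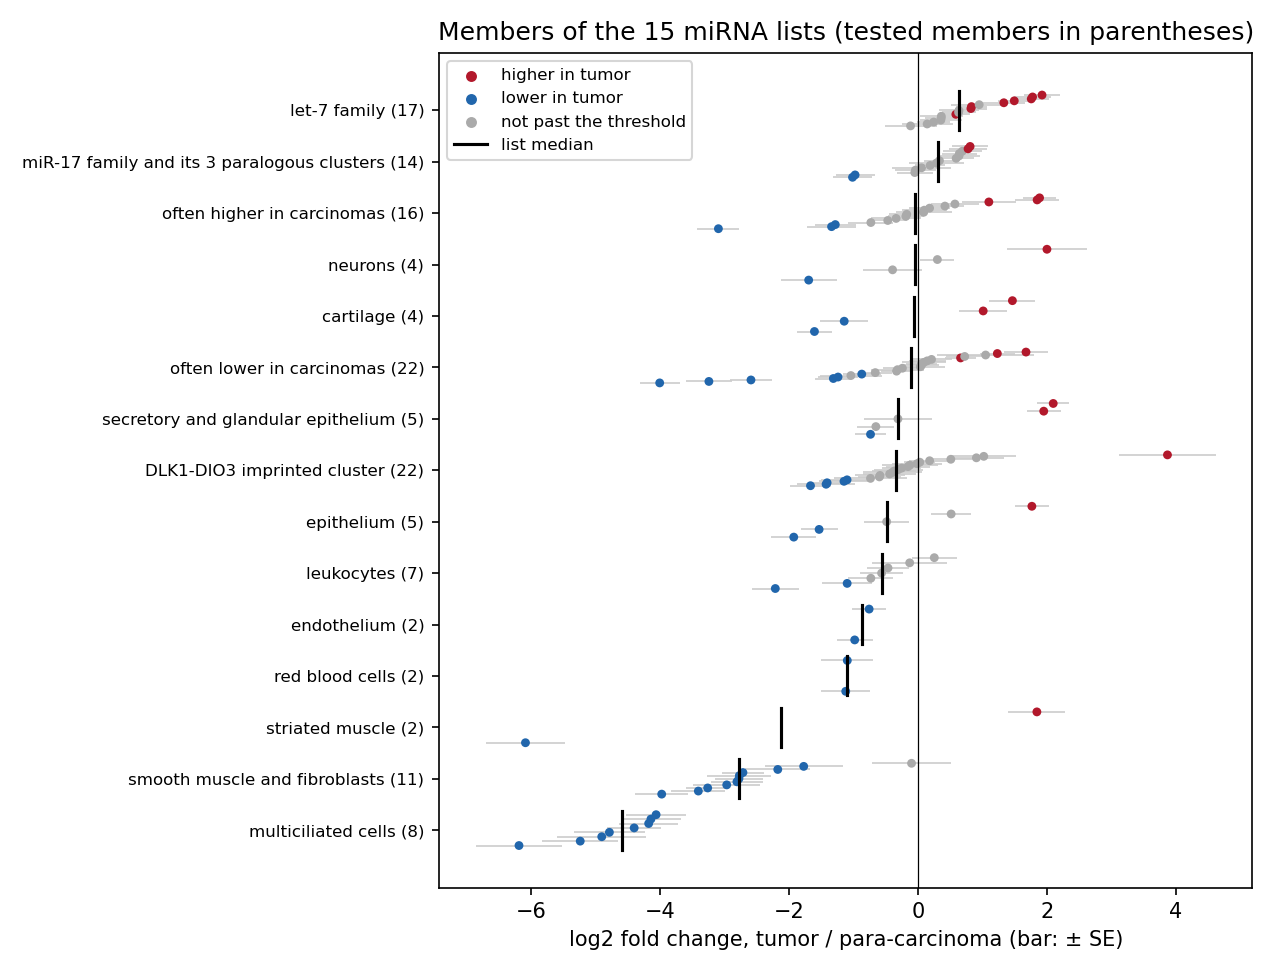
Each point is a tested member of a list, at its log2 fold change of tumor over para-carcinoma, with ± SE as a bar; the black line is the list median and color marks the call. The multiciliated list lies furthest to the left, with a median of -4.60, followed by smooth muscle and fibroblasts at -2.78.

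The let-7 family, whose members are abundant in differentiated cells, was higher in tumors. Of 17 tested members 8 rose, also adjusted over the list alone, none fell, and the median log2 fold change was 0.64. In tumors let-7a-5p rose from 20366 ± 3912 to 57357 ± 5914 CPM (1.49 ± 0.25, edgeR adjusted p = 0.00054). Both arms of let-7b rose: the 5p arm from 3702 ± 1011 to 14051 ± 2456 CPM (1.92 ± 0.28) and the 3p arm from 181 ± 22.4 to 612 ± 78.5 CPM (1.76 ± 0.27). A smaller rise was that of let-7f-5p (0.59 ± 0.22, edgeR adjusted p = 0.047), which did not pass with the goat as a block (0.058) or without any 1 of the 6 libraries (0.059 to 0.14). The list passed camera (adjusted p = 0.0051) but not with an estimated correlation (adjusted p = 0.49). With library totals 13 members were higher, at a median of 1.14.

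Among 5 secretory and glandular members, both arms of miR-148a rose, the 5p arm from 626 ± 147 to 2423 ± 150.2 CPM (1.95 ± 0.26, edgeR adjusted p = 0.00013). In the same list miR-192-5p, known from gut and kidney epithelium, fell from 3528 ± 392 to 2117 ± 381 CPM (-0.74 ± 0.24, 0.030). The values of miR-194 (-0.65 ± 0.29, edgeR adjusted p = 0.077) and miR-215-5p (-0.31 ± 0.53, named after its value was seen) did not pass, although miR-194 did with DESeq2 size factors (edgeR adjusted p = 0.044) and without the para-carcinoma library of goat 3 (0.033). Counts were the same adjusted over the list alone. The list did not pass (camera adjusted p = 0.57), and its median was -0.31 and its mean 0.47. In fry, which does not compare a list with other miRNAs, it passed as higher (adjusted p = 0.0014). With library totals miR-192-5p had an edgeR adjusted p of 0.61, and the list median was 0.22. Without the tumor of goat 1 or 3 or the para-carcinoma library of goat 2, its edgeR adjusted p was between 0.069 and 0.12.

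The epithelial miR-200 family, which keeps cells in an epithelial state, moved in both directions. In tumors miR-200c rose from 1083 ± 281 to 3687 ± 130 CPM (1.77 ± 0.27, edgeR adjusted p = 0.00029). By contrast miR-200a fell from 4493 ± 2174 to 1181 ± 139 CPM (-1.93 ± 0.35, 0.0010) and miR-429 from 9512 ± 2641 to 3284 ± 685 CPM (-1.53 ± 0.29, 0.0012). The values of miR-141, the most abundant at 38363 ± 21708 and 27387 ± 2559 CPM, and of miR-200b (named after its value was seen) were -0.49 ± 0.35 and 0.51 ± 0.31, neither past the threshold. With library totals miR-200b was higher too (1.05, edgeR adjusted p = 0.021). The list of 5 tested members did not pass (camera adjusted p = 0.99), and the counts were the same adjusted over the list alone.

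**Figure D3:**
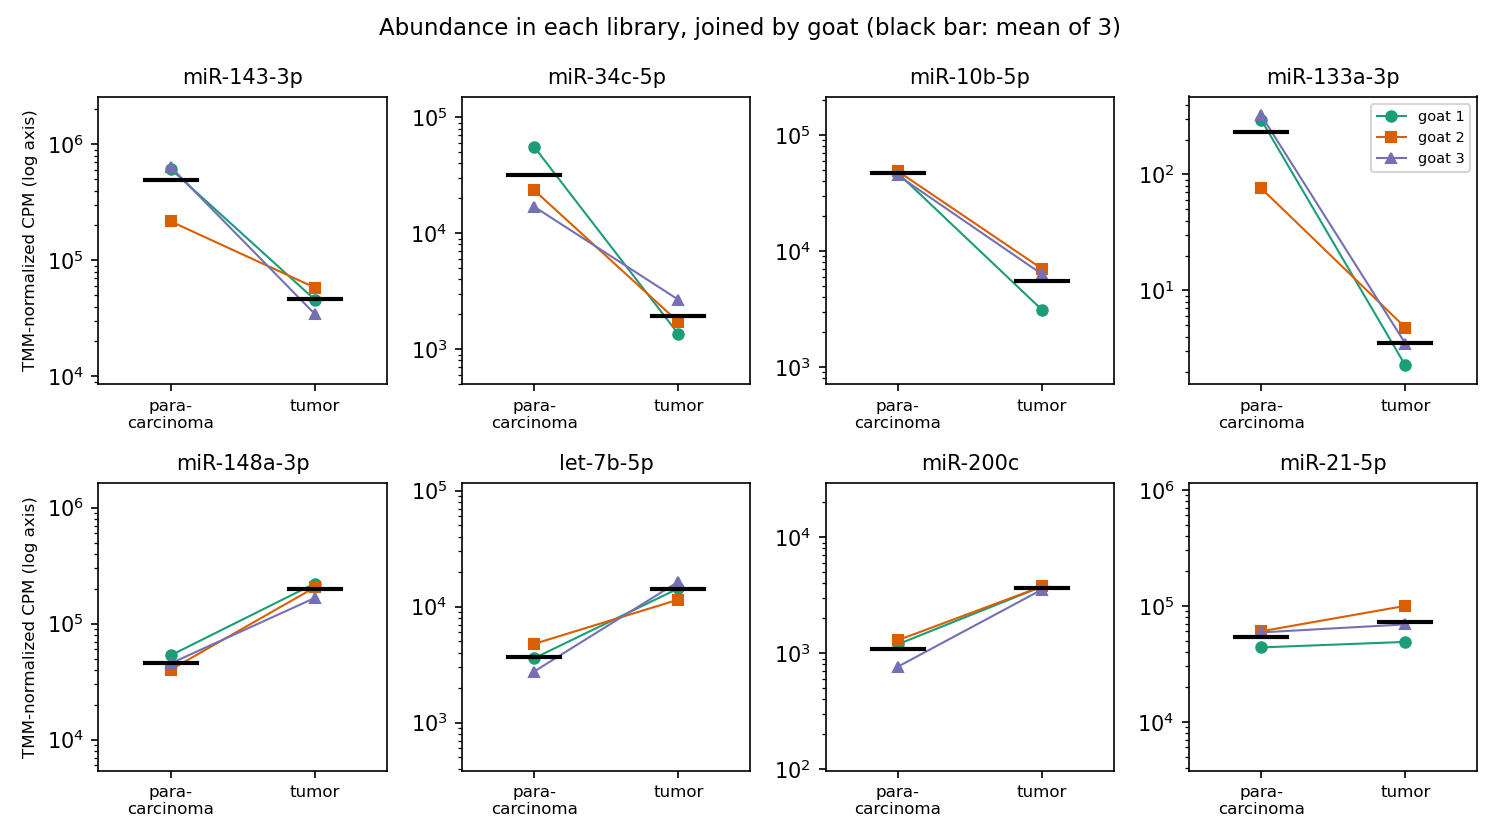
Normalized abundance (CPM, log axis, the same number of decades in each panel) of 8 miRNAs in each library; lines join the 2 libraries of a goat and black bars are means of 3. In all 3 goats miR-143-3p, miR-34c-5p, miR-10b-5p and miR-133a-3p were lower and miR-148a-3p, let-7b-5p and miR-200c higher in the tumor, while the change of miR-21-5p did not pass the test.

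The list of miRNAs often higher in carcinomas did not move as a whole (camera adjusted p = 0.99). Of 16 tested members 3 rose and 3 fell, or 2 and 3 adjusted over the list alone, and its median was -0.04 while camera's direction was up. With library totals 5 members were higher and 1 lower, at a median of 0.49. The hairpin neighbors miR-182 and miR-183 rose from 1546 ± 318 to 5718 ± 446 CPM (1.89 ± 0.25) and from 1254 ± 474 to 4519 ± 1359 CPM (1.85 ± 0.34). The hairpin between them, miR-96, had a log2 fold change of -0.47 ± 0.29 (edgeR adjusted p = 0.20), which differed from theirs by 2.36 ± 0.39 and 2.32 ± 0.45 (log2, SE). With library totals the log2 fold change of miR-96 was 0.04. The third that rose was miR-130b-5p, and besides miR-10b-5p those that fell were miR-221-3p and miR-222-3p (these 3 and miR-96 named after their values were seen). The rise of miR-130b-5p (1.10 ± 0.42, edgeR adjusted p = 0.047) was seen in goats 1 and 2, while in goat 3 the tumor had 28.7 CPM against 32.5. It did not pass with the goat as a block (edgeR adjusted p = 0.070), with DESeq2 size factors (0.078), or without any 1 library of goats 1 and 2 (0.10 to 0.18). With library totals miR-221-3p and miR-222-3p had edgeR adjusted p of 0.11 and 0.10. Without the tumor of goat 1 that of miR-221-3p was 0.065, and without the para-carcinoma library of goat 2 it was 0.068 (log2 -0.79 instead of -1.34).

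The list of miRNAs often lower in carcinomas did not pass either (camera adjusted p = 0.57), with 3 of 22 tested members higher and 6 lower, also adjusted over the list alone. With library totals 5 were higher and 3 lower, at a median of 0.40 instead of -0.10. The steepest fall was that of miR-100-5p, from 3783 ± 1046 to 235 ± 31.1 CPM (-4.01 ± 0.31, edgeR adjusted p = 1.1e-05), followed by miR-218, from 69.0 ± 18.5 to 7.03 ± 1.72 CPM (-3.24 ± 0.36). The 3 that rose were miR-204-5p, miR-16b-5p and miR-16a-5p (named after their values were seen). The call of miR-16a-5p was lost without the tumor of goat 1, 2 or 3 or the para-carcinoma library of goat 1 (edgeR adjusted p between 0.073 and 0.12). At 30206 ± 7331 and 31328 ± 6749 CPM, miR-30a-5p had a log2 fold change of 0.05 ± 0.27.

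In the miR-17 family and its paralogous clusters, which promote proliferation, 2 of 14 tested members rose and 2 fell, none of them adjusted over the list alone, and the list did not pass (camera adjusted p = 0.61). The fall was that of miR-92a-3p (-1.02 ± 0.30, edgeR adjusted p = 0.017) and miR-92b (-0.98 ± 0.30, 0.022), whose counts lay within 0.25 (log2) of each other in each library, so both values are uncertain. The rises were those of miR-19b-3p (0.81 ± 0.28, edgeR adjusted p = 0.034, with the goat as a block 0.060) and miR-19a (0.78 ± 0.29, 0.043, with the block 0.082). With library totals 7 members were higher and none lower. Without any 1 library except the tumor of goat 1, the edgeR adjusted p of miR-19b-3p was between 0.0504 and 0.13 and that of miR-19a between 0.068 and 0.14. That of miR-92a-3p was 0.059 and 0.069 without the tumor of goat 1 and the para-carcinoma library of goat 2 (log2 -0.65 without the latter, and -0.61 for miR-92b), and that of miR-92b 0.072 and 0.086, or 0.0505 without the tumor of goat 3.

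The imprinted DLK1-DIO3 cluster, a large miRNA cluster expressed from the maternal allele, had 22 tested members, of which 1 rose and 5 fell, or 1 and 3 adjusted over the list alone (camera adjusted p = 0.85). Besides the rise of miR-323b, miR-136-5p fell from 76.4 ± 21.4 to 24.1 ± 4.12 CPM (-1.67 ± 0.32) and miR-411a-5p from 211 ± 52.8 to 79.7 ± 3.62 CPM (-1.41 ± 0.28). The others that fell were miR-379-3p, miR-493-3p and miR-369-5p (named after their values were seen). With the goat as a block miR-369-5p did not pass (edgeR adjusted p = 0.070). With library totals none of these 3 passed (edgeR adjusted p between 0.18 and 0.35). Their calls were also lost with 1 library left out, at similar folds. Without any 1 tumor or the para-carcinoma library of goat 3, miR-379-3p was between -1.13 and -1.59 (-1.43 with all libraries, edgeR adjusted p between 0.051 and 0.10). Without any 1 library except the para-carcinoma library of goat 2, miR-493-3p was between -0.92 and -1.30 (-1.15 with all, edgeR adjusted p between 0.055 and 0.14). Without any 1 library except the para-carcinoma library of goat 1, miR-369-5p was between -0.92 and -1.28 (-1.10 with all, edgeR adjusted p between 0.084 and 0.15). The most abundant member, miR-127-3p, stood at 1088 ± 143 and 1110 ± 88.7 CPM (0.03 ± 0.24). With library totals the list median was 0.24 instead of -0.34, with 3 members higher and 2 lower.

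The 2 arms of a hairpin come from 1 precursor, and their ratio differed between tissues for 9 hairpins in the limma test (all named after their values were seen). The counts do not show which locus made an arm, so the cause of a changed ratio was not tested. In tumors the 5p arm lost ground to the 3p arm in miR-125b (log2 ratio change -2.40 ± 0.29, limma adjusted p = 0.0021), miR-181c (-1.997 ± 0.35), miR-335 (-1.96 ± 0.40), miR-374a (-1.67 ± 0.34), miR-99a (-1.46 ± 0.30), miR-369 (-1.34 ± 0.37) and miR-136 (-1.06 ± 0.24). It gained in miR-22 (1.52 ± 0.39) and miR-361 (1.40 ± 0.37). With the goat as a block the change of miR-369 did not pass (limma adjusted p = 0.0897). Without the tumor of goat 1, 2 or 3 the count was 1 in each case.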

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

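Summing features with near-equal counts was chosen after seeing the data; the other alternatives were fixed before. No called miRNA changed sign under any alternative that tested it, and 115 of the 137 edgeR calls were also called with the goat as a block (116 calls, 55 higher and 61 lower), 122 with DESeq2 (135 calls) and 126 with limma-voom (127 calls). The block in edgeR ended 5 calls among the 65 miRNAs named by the rule (let-7f-5p, miR-19b-3p, miR-19a, miR-455-5p and miR-126-3p), and 2 of the 9 called members named after their values were seen (miR-130b-5p and miR-369-5p), and changed no other call among them and none of the lists. DESeq2 with the block also ended those of miR-140-5p, miR-144-3p, miR-379-3p and miR-493-3p, kept that of miR-126-3p and added miR-155-5p. Without the block DESeq2 already ended 6 calls among all these named miRNAs, so not each loss came from the block. In limma with the goat as a block 11 hairpins changed arm usage, miR-369 no longer among them. An exact sign-flip permutation test of the 3 within-goat differences (mean -14.8 percentage points) gave p = 0.5 for the leading share, where 0.25 is the smallest possible. Library totals gave 106 higher and 40 lower, a difference set by the median shift of 0.54. An adjusted p below 0.01 left 39 higher. Leaving out a library or a goat gave 32 to 58 higher, with fewer samples in each fit; of 55 calls named by the rule, 40 held without any 1 library, and of the 9 others 3; in 5 of 80 such losses the log2 fold change was smaller by over 1.5 times. Arm usage calls ranged from 1 to 9 with 1 library left out, and the cause was not tested beyond the fewer samples.

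With camera's estimated correlation 0 lists passed (2 at an unadjusted p under 0.05; fry called 4, the fourth being the secretory and glandular list at 0.0014): the adjusted p was 0.494 for let-7, and 0.282 for both multiciliated cells and smooth muscle and fibroblasts. Under the other scalings, filters, block, fry, summed features and left-out libraries or goats, for which lists were tested, these 3 passed, with adjusted p of at most 0.017, 0.0053 and 0.0014. Lists that did not pass, and whose direction turned, never passed: for the often higher list fry gave 0.762 and no filter 0.942, and leaving out libraries 0.877 to 0.988. Left-out ranges were 0.656 to 0.988 for epithelium, 0.877 to 0.990 for cartilage and 0.622 to 0.988 for DLK1-DIO3. For neurons fry gave 0.762, scaling without the 3 most abundant 0.985, summed features 0.981 and left-out libraries 0.738 to 0.990. The cause of these turns was not tested. Among miRNAs that did not pass, log2 fold changes with libraries left out ranged from -0.12 to 0.24 for miR-30a-5p, -0.69 to 0.091 for miR-141 and -0.10 to 0.13 for miR-127-3p. The range was -0.90 to 0.13 for miR-215-5p and -0.90 to 1.08 for miR-424-5p, which was at 0.072 with the block, 0.0046 with scaling without the 3 most abundant, 0.11 with DESeq2 and the block and 0.16 with limma-voom. With library totals miR-146b-5p was at 0.089, miR-128-5p at 0.16, miR-96 at 0.039, miR-215-5p at 0.22 and miR-424-5p at 0.35, and with DESeq2 size factors miR-127-3p at -0.0035. Pseudocounts for normalized values were not run, because the files hold counts. Depth limits the miRNAs with few reads in a group, such as miR-323b, miR-873-3p, miR-331-3p, miR-449a-3p and miR-449c.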

Other observations

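The sets in the next paragraphs, and the tests of even dilution, reads left by miR-143-3p, cell mix, shared family reads and near-equal counts, were chosen after the results were seen. Hairpins that lie within 10 kb of each other tended to change together. Over 56 neighboring pairs the median difference of log2 fold changes was 0.347, against 1.25 for random pairs of the same miRNAs (one-sided permutation p = 1e-04, the smallest that 10000 permutations give). Of 23 clusters tested with camera, 6 passed. The miR-34b/c cluster (4 of 4 tested lower, median -4.16), the miR-449 cluster (4 of 4, -5.07), the miR-199a and miR-214 cluster (4 of 4, -2.89) and the miR-143 and miR-145 cluster (3 of 3, -3.41) were lower. Higher were the let-7a and let-7b cluster (4 of 4, 1.77) and the cluster of miR-660, miR-500, miR-362 and miR-502b (5 of 6, median 1.25, camera adjusted p = 0.036). With an estimated correlation none passed (adjusted p of 0.56 for the first 5 and 0.61 for the last). The first 5 hold only members of the multiciliated, smooth muscle and fibroblast, and let-7 lists, so they repeat those list results.

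Contig-named features rose more often than those with a goat name. Of 31 tested, 17 rose and 1 fell, against 53 rises among 244 miRNAs with a goat name (Fisher's exact p = 0.00025, across features, which are not independent replicates). Their median log2 fold change was 0.92 with TMM and 1.51 with library totals (camera p = 0.0033, or p = 0.041 with an estimated correlation). The rises numbered 12 with the goat as a block and 23 with library totals. With 1 library left out they numbered 10 to 13, the lowest being without the tumor or the para-carcinoma library of goat 1. They held between 1.49% and 3.94% of the reads of a library. The 31 tested are not all separate. Some differ in name only by a star suffix, NC_022318.1_739, NC_022318.1_745 and NC_022318.1_749 had similar tumor abundances, and NC_022303.1_70 and NC_022308.1_289 had near-equal counts. The number of distinct sequences behind the 17 rises is therefore not known. Among features not singled out by the rule, miR-122, known from liver, had 170 reads in the para-carcinoma library of goat 2 and 0 to 15 in the other libraries. The muscle miRNA miR-1, too low to be tested, had 46, 6 and 16 reads in the para-carcinoma libraries of goats 1 to 3 and 0, 1 and 0 in the tumors. For miR-29c the 5p arm had 21 to 119 reads per library and the 3p arm 0 to 5.

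Lists of several non-tumor cell types had lower members in tumors, by unequal amounts: mean log2 fold changes over the 3 goats were -4.56 ± 1.04 (SD) for multiciliated cells, -2.57 ± 0.43 for smooth muscle and fibroblasts, -1.20 ± 0.50 for red blood cells, -0.87 ± 0.25 for endothelium and -0.67 ± 0.22 for leukocytes. Not all such lists fell: striated muscle was at -1.90 ± 0.61, but cartilage at -0.10 ± 0.093 and neurons at 0.013 ± 0.38. With library totals the list medians of red blood cells, endothelium and leukocytes were -0.54, -0.34 and -0.10. Even dilution of all other cells by tumor cells would lower these lists alike if tumor cells held none of their miRNAs. The multiciliated mean lay below the endothelial mean, which rests on the 2 arms of miR-126, by more than 2 SD (difference -3.69 ± 1.28). Expression in tumor cells was not measured, so this argues only against dilution without such expression. The share of reads left by miR-143-3p rose by 0.65 ± 0.36 (log2, SD), which would raise other miRNAs in tumors, and the 2 leading lists lay at least 2.60 ± 0.36 below that with library totals (difference -2.60), while a test by other scalings (highest list median -2.25) moved miRNAs too little to decide. A different mix of cells, with unequal loss of each type, may account for the pattern, in which the means of the 2 leading lists differed by -1.99 ± 1.09, but with no cell counts this was not tested and it cannot be told apart from lower expression within cells, and the tumor itself, as the design names it, also stays open.

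Some hairpins of the 2 miR-200 clusters moved apart. The ratio of miR-200c to its neighbor miR-141 rose by 2.15 (log2) in tumors and that of miR-200b to miR-200a by 2.38, with no overlap between groups, as chance gives in 10% of such comparisons. The ratio of miR-200a to its neighbor miR-429 changed by only -0.30, with overlapping groups. Full sharing of reads among near-identical family members would pull miR-200b, miR-200c and miR-429 together, yet their log2 fold changes spanned 3.30 ± 0.39 (SE). Sharing in part, or between only 2 members, can leave such a span and is not excluded. The test did not cover miR-141 and miR-200a. The usual scatter between neighboring hairpins cannot be excluded: the second largest difference in these clusters was 2.25 ± 0.44 (SE), against a 90th percentile of 1.87 over 53 other pairs. Different processing or decay of the hairpins may also play a part and was not tested.

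Near-equal counts in every library, within 0.25 (log2) and with at least 100 reads, were found in 4 groups of features among 7381 pairs. For miR-92a-3p and miR-92b and for the contig-named NC_022303.1_70 and NC_022308.1_289 the departure from an even split was within sampling noise (chi-square per degree of freedom 1.03 and 0.937), consistent with reads of 1 sequence assigned at random to 1 of its features. For miR-93-5p and miR-127-3p it was 6.03, which argues against that explanation, and for miR-199a-3p with miR-199b-3p and miR-199c-3p it was 1.96 (permutation p = 0.024 over 100000 random reassignments of the reads), beyond sampling noise but below the bound of 2 set against it, so for these it stays open. Counting each read for every feature it matches would give equal counts where all reads match each feature of a group. Of 24 comparisons 0, or 0 percent, were exactly equal, which argues against that case. Where only part of the reads match each feature, counts need not be equal, so there the comparison cannot decide. The miRNA annotation behind the counts was not used here, so the sequences were not compared, and no biological explanation was tested.

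The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05, and only 4 of these, the real one included, keep 1 library of each goat on each side, while the other 6 keep both libraries of 1 goat together. The real split gave 137 miRNAs past the threshold in edgeR and 1 of 10 splits gave as many, the highest other count being 0 (6 at an unadjusted p under 0.05, against 161). The real split gave 9 hairpins with changed arm usage in limma, also in 1 of 10, with 0 as the highest other (3 at an unadjusted p under 0.05, against 19). The real split gave 3 lists past camera at the preset correlation, but 5 of 10 splits gave as many, the highest other giving 5. Among the 4 splits that part all goats, 2 gave as many lists, the highest other giving 3, and the highest other counts of miRNAs and hairpins were 0. Every split but the real one has both tissues on each side, so the tissue difference widens the spread there. The low counts of miRNAs and hairpins in those splits therefore follow largely from the design and do not measure false calls.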
